A study of Homo sapiens with 8 samples.

How the data were processed

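Bulk RNA-seq of total RNA from human bone marrow-derived MSCs was deposited as 1 table of RPKM per gene (reads scaled to gene length and library total, the authors' unit) for 8 libraries, 2 each of control, MoS2, NIR and NIR + MoS2. Per the submitters' processing notes, base calls were converted with bcl2fastq and reads were aligned to hg38 with STAR, with no versions given. The program that counted reads, the gene annotation and the strand setting are not given in the sources used here. Groups were taken from the sample labels, which give a number to each replicate but do not say that equal numbers share a culture or a donor. For this reason the numbers were not used as pairs except as an alternative. Deviations from the group means correlated between equal numbers at -0.366 to 0.204 across genes, with no common sign. However, control replicates 1 and 2 correlated best with NIR replicates 1 and 2 (r = 0.985 and 0.990). NIR + MoS2 replicates 1 and 2 correlated best with MoS2 replicates 1 and 2 (both 0.988). The MoS2 libraries correlated best with each other (0.989), and NIR replicate 1 with NIR replicate 2 (0.988). A structure shared by equal numbers therefore stays open.

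The table held 19479 genes. Y-linked genes and XIST, 47 in all, were left out, which left 19432, and 27 symbols that a spreadsheet had turned into dates were restored from their Entrez IDs. Positions are those of GENCODE release 29 on GRCh38, in which 19386 genes were matched. Whole reads were worked out from the steps between RPKM values, which gave whole reads in every library for 15498 of 15499 genes above 0, within a tolerance of 0.003 reads. Of the gene lengths found this way 83.2% were multiples of 3, so RPKM appears to have been computed over coding length. For 144 genes, HSPA1A among them, the step was a whole fraction of a read. Read totals ranged from 7795701 to 11245522 per library, and about 99.7% of each total lay in the table. Differences between replicates exceeded sampling noise in each group, with a chi-square per degree of freedom of 24.2 for control, 15.6 for MoS2, 11.5 for NIR and 24.5 for NIR + MoS2.

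Genes with an RPKM of at least 1 in at least 2 libraries were tested (11359 genes), on log2(RPKM + 1), with limma 3.58.1 (trend) in R 4.3.3. One fit of the 4 group means to the 8 libraries, with 4 residual degrees of freedom, gave 8 comparisons: each treated group against control, NIR + MoS2 against MoS2 and against NIR, the interaction, the MoS2 average over light and the NIR average over MoS2. P-values were two-sided, adjusted by Benjamini-Hochberg within each comparison, and called under 0.05. Of 39 gene lists 35 had at least 5 tested members and were tested with camera at its preset correlation of 0.01, with an estimated correlation, and with fry, which asks whether a list's genes move on balance 1 way and does not compare them with other genes. Of 99 list calls with the preset correlation 4 held with an estimated one, the NF-kB and the histone lists in NIR + MoS2 against MoS2 and in the NIR average. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the table and drew the plots.

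The fit, the filter, the threshold, the comparisons, the lists, the marker genes and the rule for naming genes were chosen before the data were examined. The rule named the 12 highest rises and 12 deepest falls among called genes whose treated libraries both lay outside the control range, for each treated group against control, and 6 and 6 for the other comparisons. Where no gene was called it named the 5 smallest p-values, and it passed over uncharacterized, antisense, read-through and pseudogene symbols. Up to 4 members per called list and HSPA1A, HMOX1, MT1X, IL6, COL1A1, ITGB1 and MKI67 were named in addition. Alternatives chosen beforehand were a pseudocount of 0.25, no filter on low values, a mean RPKM of at least 5, median centring, the replicate number as a block, only the 2 groups compared, and leaving out each library. Where a left-out library leaves a group with 1 library, that library is assumed to vary like the other groups. Alternatives added after seeing the data were voom on the recovered reads, reads thinned to the smallest library (5 draws) and a correction for GC content and length (11322 genes). The alternatives were first recorded for more genes, and were limited to the genes named by size, by p, as markers or as called list members after those values had been seen.

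The pipeline was tested on simulated data with 200 changed genes. For NIR + MoS2 against control it recovered 2% of genes with a true log2 change of 0.5, 60.0% at 1, 88% at 1.5 and 96% at 2, with 15 false calls among 138. For the MoS2 average it recovered 34%, 94%, 100.0% and 96%, with 15 false calls among 177, and with no changed genes it made 0 calls in both (limma). The false calls were above the share that the threshold allows, 0.05. Beside counting noise, the simulation gave each gene the same coefficient of variation, 0.131, taken from well-expressed genes. It held no shifts of whole libraries. In the real data the 2 NIR + MoS2 libraries had median shifts from the gene means of 0.234 and 0.042. The simulated rates may therefore not hold for the real libraries. Erythroid, mitochondrially encoded and small noncoding lists had 0 tested members and the endothelial list 2, so these were left out of the list tests. Reads and sequence files were not available, so alignment and counting were not repeated.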

Results

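Total RNA from human bone marrow-derived mesenchymal stromal cells (MSCs) was sequenced in 8 bulk libraries, 2 in each of 4 groups. The groups were control, MoS2 (molybdenum disulfide nanosheets at 25 µg/mL for 48 hours), NIR (low-intensity near-infrared light) and NIR + MoS2 (both), with RNA taken on day 7 of culture. MoS2 nanosheets are thin flakes that absorb near-infrared light and turn it into heat. Read totals worked out from the deposited RPKM values were 11245522 and 8922517 for control, 9762327 and 8043357 for MoS2, 8963568 and 10227133 for NIR, and 7795701 and 10921082 for NIR + MoS2. A total of 11359 genes entered the tests. The labels do not say that the replicates are separate cultures or donors, so p-values measure only the spread between these samples, which may be technical.

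The collagen gene COL1A1 and the inflammatory gene CXCL8 show the range of change across the groups. COL1A1 (RPKM mean ± SD, n = 2) was at 9132 ± 1566 in control, 10099 ± 348 in NIR, 4051 ± 1446 in MoS2 and 3486 ± 938 in NIR + MoS2. CXCL8 was at 1.03 ± 0.629, 5.54 ± 6.27, 15.4 ± 8.89 and 83.2 ± 54.4 in the same order. On principal component 1, which held 44.9% of the variance, the 4 libraries with MoS2 lay between 4.75 and 37.6 and the 4 without it between -31.2 and -9.45. The 10 genes with the most reads in each library took 18.1 to 19.4% of the reads in control and NIR and 12.1 to 15.1% in MoS2 and NIR + MoS2. The log2 change of the median gene was 0.17 for MoS2 against control, 0.23 for NIR + MoS2 against control, 0.23 for NIR + MoS2 against NIR, 0.21 for the MoS2 average over light, 0.051 for NIR + MoS2 against MoS2, 0.053 for the interaction, 0.031 for the NIR average and 0.0031 for NIR against control. Log2 changes are given relative to the median gene of the same comparison unless said otherwise, on the log2(RPKM + 1) scale, which understates changes of low genes. The limma tests used the values as deposited. The numbers of genes called after each library was centred on its median difference are given beside them. Counts of list members passing over all genes are as deposited, and some of these members lost their calls after centring.

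**Figure D1:**
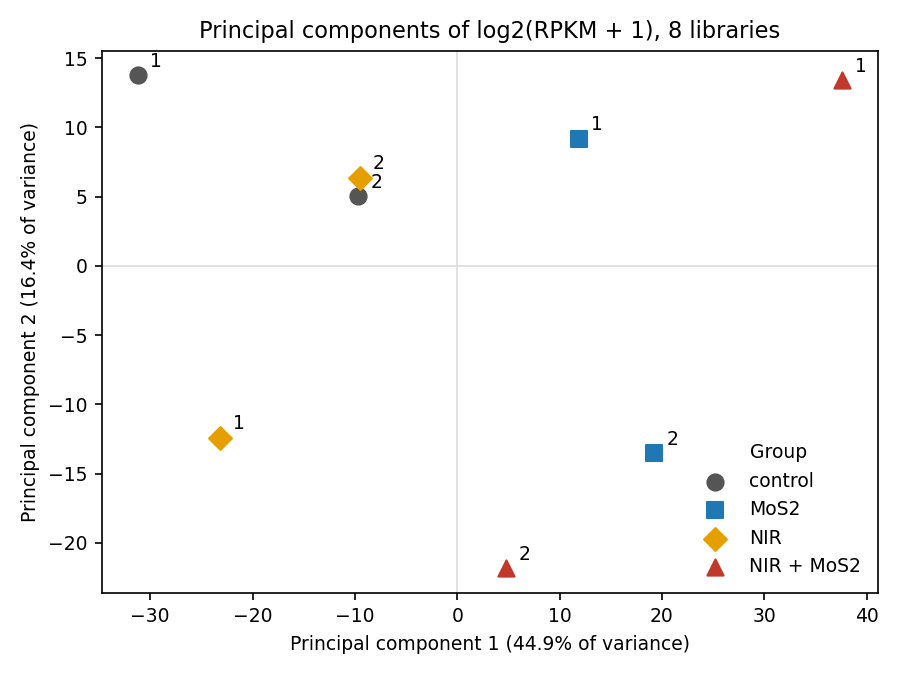
Principal components 1 and 2 of log2(RPKM + 1) for the 8 libraries, with the percent of variance on each axis; color and shape give the group and the digit gives the replicate. The 4 libraries with MoS2 lie at 4.75 or above on component 1 and the 4 without it at -9.45 or less.

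MoS2 against control compares cells with and without nanosheets, both without light. Among the genes that limma called, the highest rise was in AKR1C1, an aldo-keto reductase of the NRF2 antioxidant program, at 2.05. FTH1, the heavy chain of the iron store ferritin, rose by 1.15. GPNMB, a glycoprotein of lysosomes and the cell surface, rose by 1.93 and SPP1, the matrix phosphoprotein osteopontin, by 1.76. TNFSF4, a costimulatory ligand of T cells, rose by 1.71, the secreted folate receptor FOLR3 by 1.97, the transcription factor RFX8 by 1.53, the annexin ANXA10 by 1.49, the vesicle GTPase RAB8B by 1.45 and the chromatin protein HMGA1 by 0.91. Lower genes included the acute-phase gene SAA1, which changed by -1.94, the kisspeptin precursor KISS1 by -1.91, the transcription cofactor LBH by -1.85 and CNN1, a calponin of contractile cells, by -1.32. These were the 14 genes that limma called, 10 higher and 4 lower, with adjusted p from 0.0124 for GPNMB to 0.047 for RFX8. For each of the 14 genes 2 of 2 MoS2 libraries lay beyond both controls. The inflammatory gene CXCL8 was not among the 14, with 27 and 53 reads in the MoS2 libraries and 2 and 4 in the controls. At an unadjusted p under 0.05 there were 1570 genes, with 567.95 expected by chance, and voom called 15, with 8 of the 14 among them and FOLR3 (adjusted p = 0.0983), TNFSF4 (0.0903), RFX8 (0.0575), ANXA10 (0.0575), RAB8B (0.0964) and SAA1 (0.156) not. After centring 42 genes were called, 11 higher and 31 lower, with 12 of the 14 among them and FTH1 (adjusted p = 0.0761) and HMGA1 (0.072) not. Without control replicate 1 or without MoS2 replicate 2 the count was 0 and the 14 genes lost their calls, GPNMB with an adjusted p of 0.135 and 0.331, and without control replicate 2 the count was 523. Without MoS2 replicate 1 TNFSF4 (0.0537), RFX8 (0.080), RAB8B (0.127), HMGA1 (0.0537) and SAA1 (0.0911) lost theirs. Without the filter on low values 0 genes were called, GPNMB with an adjusted p of 0.256, the GC and length correction gave 35, where LBH was not called (0.0603), and the replicate block gave 28.

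Of 35 lists 16 were called in MoS2 against control with the preset correlation, 4 higher and 12 lower, and 0 with an estimated correlation. Fibrillar and basement membrane collagens were called lower, with a median change of -0.81 over 20 tested genes (camera adjusted p = 2.27e-17 with the preset correlation, adjusted p = 0.211 with an estimated correlation). Of these collagens 12 were lower adjusted over the list alone and 0 over all genes tested. COL1A1, the main chain of type I collagen, was at -1.38 with an adjusted p of 0.0942, and it was called by voom (0.0475), without control replicate 2 (0.0342) and without MoS2 replicate 1 (0.022). Smooth muscle and myofibroblast markers had a median of -0.71 over 16 genes (adjusted p = 5.64e-14; adjusted p = 0.176 with an estimated correlation), with 5 lower adjusted over the list alone and CNN1 over all genes. The NRF2 antioxidant genes had a median of 0.23 over 31 genes (adjusted p = 2.81e-06; adjusted p = 0.211 with an estimated correlation), with 12 higher adjusted over the list alone and 2, AKR1C1 and FTH1, over all genes. The glycolysis and hypoxia genes had a median of -0.36 over 32 genes (adjusted p = 6.79e-08; adjusted p = 0.211 with an estimated correlation), and 0 of them passed either adjustment.

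NIR against control compares cells with and without light, both without nanosheets. ARC, an immediate-early gene of synapses that cells switch on within minutes of a stimulus, was at 2.25, with 103 reads in the NIR libraries and 3 in the controls, a ratio of 36.1 (95% exact interval 12 to 178). The intermediate filament gene NEFM was at -1.37, the mitochondrial assembly factor FMC1 at 1.26, the histone HIST1H2AE at 1.51 and KISS1 at -1.07. These 5 had the smallest p-values, and limma and voom each called 0 genes. At an unadjusted p under 0.05 limma gave 237, fewer than the 567.95 expected by chance. Genes are not independent, so such counts can lie far from that number on either side. The smallest adjusted p was that of ARC, 0.0515, which became 0.0175 after centring, 0.035 with a pseudocount of 0.25 and 0.0347 with the replicate block, so that 1 gene was called in each, and a fit to only the 2 groups called 2. Replication-dependent histones had a median of 0.31 over 14 genes (camera adjusted p = 2.03e-06 with the preset correlation, adjusted p = 0.157 with an estimated correlation), with 2 higher adjusted over the list alone. Intervals and limits on read ratios cover counting error only.

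Of the lists tested in NIR against control 6 were called with the preset correlation, 5 higher and 1 lower, and 0 with an estimated correlation. NRF2 antioxidant genes had a median of 0.13 (adjusted p = 0.00228; adjusted p = 0.887 with an estimated correlation), with 1 higher adjusted over the list alone, and lost the call without control replicate 2 (0.111) and NIR replicate 1 (0.118). In this list AKR1C1, chosen for this comparison after its values were seen, was at 1.23 and HMOX1 at 0.59 (adjusted p = 1.00), both higher in 2 of 2 NIR libraries and neither called. Cytosolic ribosomal protein genes had a median of 0.088 (adjusted p = 0.0034) and nuclear-encoded oxidative phosphorylation genes 0.083 (0.0034), with calls lost without control replicate 1 (0.85 and 0.85) and NIR replicate 1 (0.225 and 0.616) and after the GC and length correction (0.164 and 0.0709). Cell cycle and mitosis genes had a median of 0.16 (0.011), lost without control replicate 1 (0.942) and NIR replicate 2 (0.178). Glycolysis and hypoxia genes had a median of -0.12 (0.0143), lost without control replicate 1 (0.102), control replicate 2 (0.154) and NIR replicate 1 (0.232). For these last 4 lists adjusted p = 0.887 with an estimated correlation, and 0 members passed over all genes.

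NIR + MoS2 against control compares cells given both treatments with untreated cells. The neutrophil chemokine CXCL8 rose by 5.01 (SE 0.63, adjusted p = 0.00147), from 6 to 510 reads, of which 106 and 404 were in the 2 NIR + MoS2 libraries. The cytokine IL1B rose by 2.4, the monocyte chemokine CCL2 by 1.69, the kinin receptor BDKRB1 by 1.85 and the cytokine TSLP by 1.83. Antioxidant genes rose, AKR1C1 by 2.49, the heme-degrading enzyme HMOX1 by 1.31 and FTH1 by 1.38. The protease inhibitor TFPI2 rose by 2.26, the endothelial proteoglycan ESM1 by 2.15, SPP1 by 2.14, ANXA10 by 2.12, GPNMB by 2.02, ARC by 1.99 and RFX8 by 1.82. Among lower genes LBH changed by -2.73, KISS1 by -2.68, the hyaluronan-degrading protein CEMIP by -2.25, SAA1 by -2.14, the smooth muscle phosphatase inhibitor PPP1R14A by -2.13, the muscle small heat shock protein HSPB7 by -2.06, smooth muscle actin ACTA2 by -1.48 and COL1A1 by -1.64.

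CXCL8, AKR1C1 and LBH were among 133 genes that limma called in this comparison, 95 higher and 38 lower, against 57 higher and 109 lower after centring, with 94 genes shared. For genes named by size the naming rule required 2 of 2 NIR + MoS2 libraries beyond both controls. Of the genes given above, CCL2, HMOX1, FTH1, ACTA2 and COL1A1 were named as markers or list members and had this as well. The rule also named EFHD1, FLG, CLIC3, SAA2, IGSF23 and NXPH3 as falls, and their calls did not hold in every leave-out. voom called 142 genes, but not TSLP (adjusted p = 0.0559), SAA1 (0.0606), SAA2 (0.173) or EFHD1 (0.0894). Without the filter on low values 0 genes were called and the named genes lost their calls, CXCL8 with an adjusted p of 0.0893, AKR1C1 with 0.0507 and LBH with 0.0516, while the GC and length correction gave 394. The count was 15 without control replicate 1, 769 without control replicate 2, 40 without NIR + MoS2 replicate 1 and 203 without NIR + MoS2 replicate 2. Without control replicate 1 the call was lost for IL1B (adjusted p = 0.0614), TSLP (0.178), FTH1 (0.0857), ESM1 (0.0961), ARC (0.0636), RFX8 (0.0705), CEMIP (0.13), SAA1 (0.0701), PPP1R14A (0.202), HSPB7 (0.158) and COL1A1 (0.175). Without NIR + MoS2 replicate 1 it was lost for TSLP (0.139), PPP1R14A (0.167), HSPB7 (0.109) and COL1A1 (0.171). CXCL8, AKR1C1, HMOX1, CCL2, TFPI2, SPP1, ANXA10, GPNMB, BDKRB1, LBH, KISS1 and ACTA2 kept theirs in all 4 leave-outs.

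With the preset correlation, and not with an estimated one, the inflammatory, antioxidant and cell cycle lists were called higher in NIR + MoS2 against control and the collagen and contractile lists lower. NF-kB and inflammatory cytokine genes had a median of 0.43 over 28 genes. Camera gave an adjusted p of 1.52e-05 with the preset correlation and 0.0933 with an estimated one. Adjusted over the list alone 13 were higher, and over all genes 6, among them CXCL8, IL1B and CCL2. Of the 6, CCL5 (limma adjusted p = 0.0715), CXCL2 (0.0753) and TNFAIP6 (0.0727) were not called after centring. NRF2 antioxidant genes had a median of 0.31 (adjusted p = 1.80e-08; adjusted p = 0.143 with an estimated correlation), with 19 higher adjusted over the list alone and 8 over all genes. Collagens had a median of -0.85 (adjusted p = 1.23e-17; adjusted p = 0.144 with an estimated correlation), with 12 lower adjusted over the list alone and 5 over all genes. Smooth muscle and myofibroblast markers had a median of -0.85 (adjusted p = 7.38e-19; adjusted p = 0.0933 with an estimated correlation), with 10 lower adjusted over the list alone and 3 over all genes. Cell cycle and mitosis genes had a median of 0.46 over 37 genes (adjusted p = 1.49e-07; adjusted p = 0.257 with an estimated correlation), with 20 higher adjusted over the list alone and 1 over all genes.

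Of 35 lists 16 were called in NIR + MoS2 against control with the preset correlation, 5 higher and 11 lower, and 0 with an estimated correlation. Epithelial markers had a median of -0.56 over 9 genes (adjusted p = 1.22e-06; adjusted p = 0.0933 with an estimated correlation), with 2 lower adjusted over the list alone and 1, the keratin KRT7, over all genes. KRT7 was at -1.44 (adjusted p = 0.0173) and lost its call without control replicate 1 (0.145), without NIR + MoS2 replicate 1 (0.167) and without the filter (0.115). Cytosolic ribosomal protein genes, an RNA quality list, had a median of 0.066 over 76 genes (adjusted p = 0.00414; adjusted p = 0.786 with an estimated correlation), with 0 passing over all genes. The ribosomal call was lost after centring (0.24) and without control replicate 1 (0.274), and without NIR + MoS2 replicate 2 the list turned lower (0.679).

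**Figure D2:**
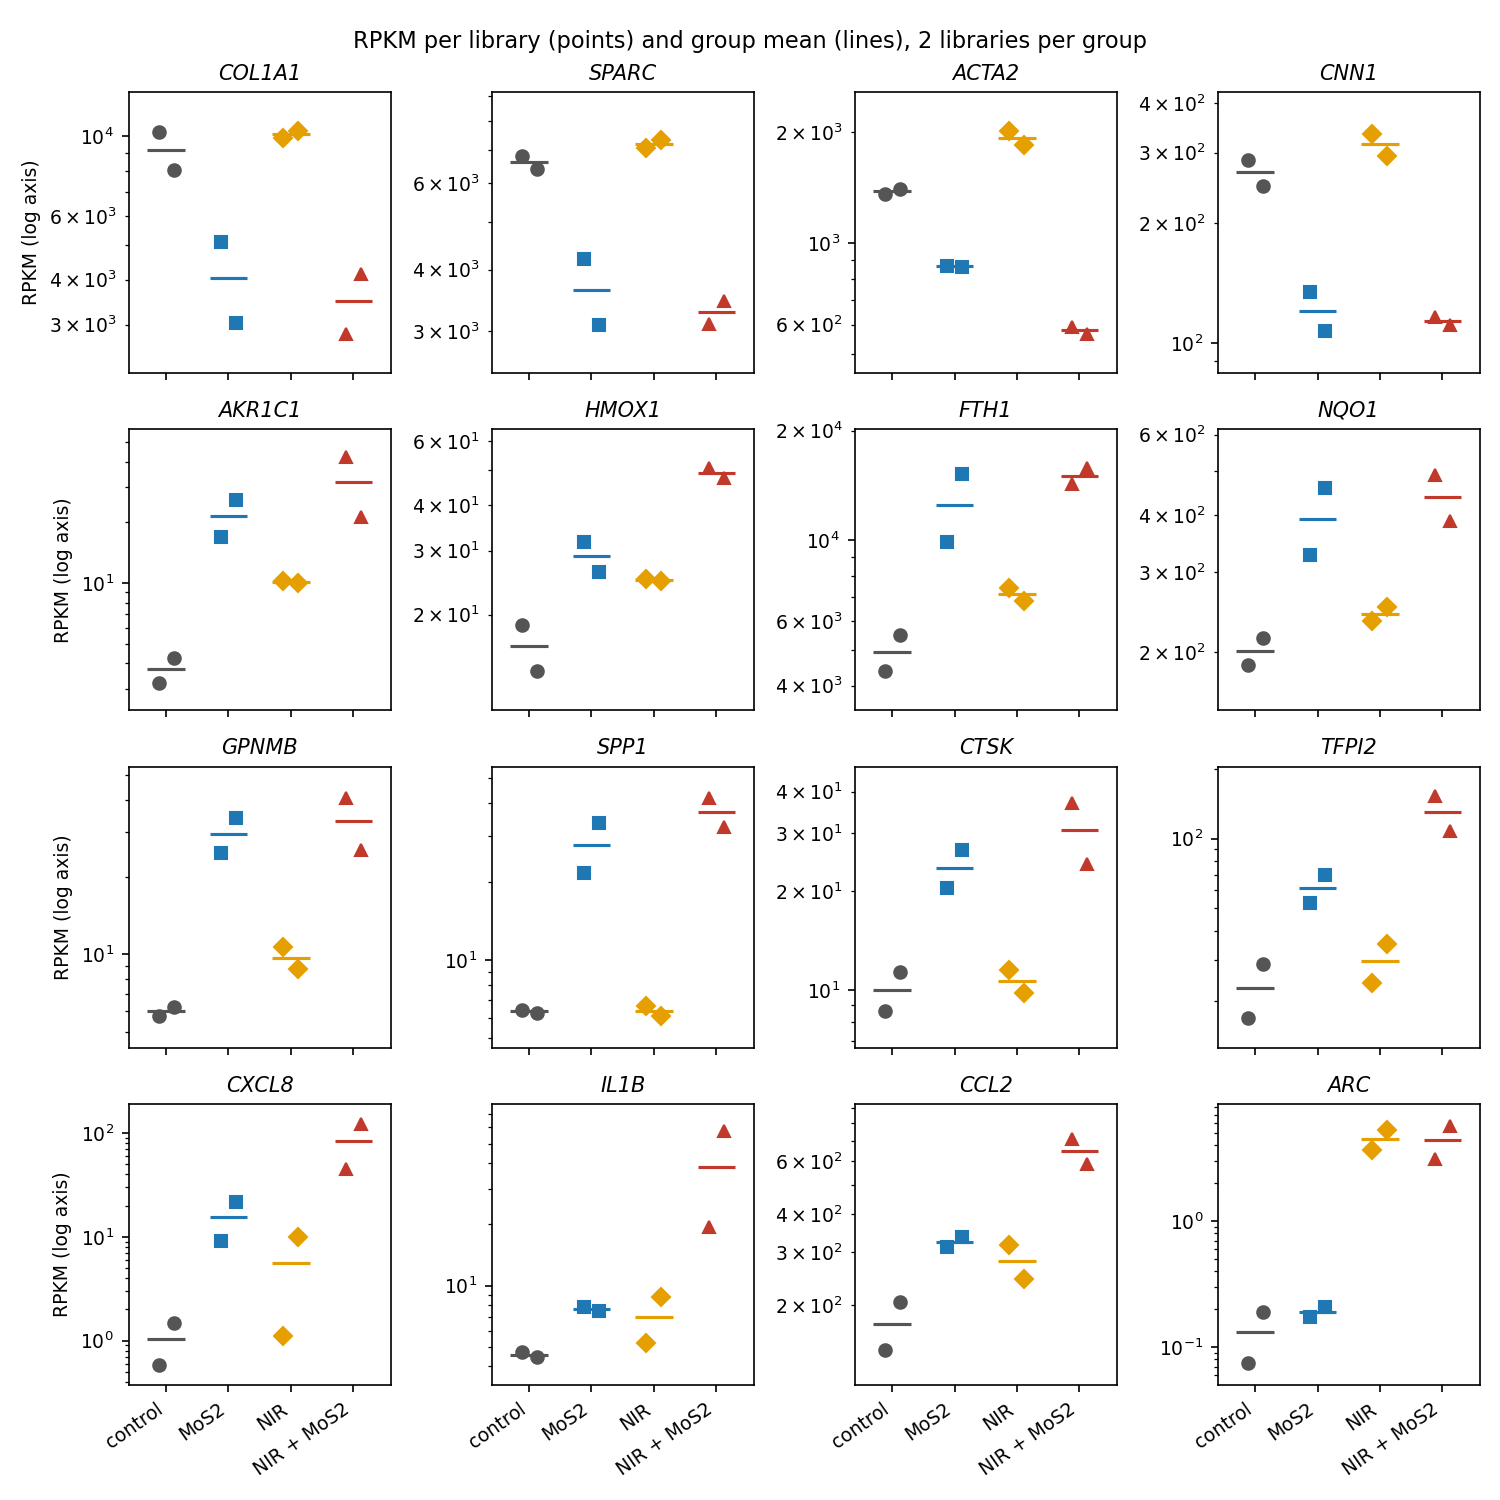
RPKM on a log axis for 16 genes in the 8 libraries; points are libraries and lines are group means (n = 2). COL1A1, SPARC, ACTA2 and CNN1 are lower in the 4 libraries with MoS2, and ARC is higher in the 4 libraries with NIR.

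NIR + MoS2 against NIR compares cells with and without nanosheets, both under light. CXCL8 rose by 3.73, ESM1 by 2.73, SPP1 by 2.13, DUSP6, a phosphatase that switches off ERK, by 2.01, IL1B by 1.91 and TFPI2 by 1.88. Among lower genes PPP1R14A changed by -2.53, the chloride channel protein CLIC3 by -2.43, SAA1 by -2.2, HSPB7 by -2.17, ACTA2 by -1.96 (adjusted p = 0.00067) and COL1A1 by -1.79. The water channel AQP1 changed by -2.36, from 72 to 2 reads, and the adipokine LEP by -2.34, from 37 reads to 1. limma called 77 genes, 39 higher and 38 lower, against 29 higher and 89 lower after centring, with 67 shared, and voom called 86, without AQP1 (adjusted p = 0.056), LEP (0.126) and SAA1 (0.071). For genes named by size the naming rule required 2 of 2 NIR + MoS2 libraries beyond both NIR libraries. ACTA2 and COL1A1, named as a list member and a marker, had this as well. Without the filter 1 gene, ACTA2, was called, and CXCL8 (0.172), SPP1 (0.0715) and the other named genes lost their calls, while the GC and length correction gave 193. The count was 21 without NIR + MoS2 replicate 1, 165 without NIR + MoS2 replicate 2, 6 without NIR replicate 1 and 40 without NIR replicate 2.

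ESM1, SPP1, CLIC3 and ACTA2 kept their calls in NIR + MoS2 against NIR whichever library was left out. Without NIR replicate 1 the call was lost for CXCL8 (adjusted p = 0.0808), DUSP6 (0.0808), IL1B (0.274), TFPI2 (0.0636), PPP1R14A (0.163), AQP1 (0.211), LEP (0.274), HSPB7 (0.222) and COL1A1 (0.163). Without NIR + MoS2 replicate 1 it was lost for PPP1R14A (0.0726), AQP1 (0.0794), LEP (0.106), HSPB7 (0.104) and COL1A1 (0.148). SAA1 lost it without NIR replicate 2 (0.0563), as did COL1A1 (0.114) and LEP (0.16), and LEP also without NIR + MoS2 replicate 2 (0.062). Smooth muscle and myofibroblast markers had a median of -0.86 (camera adjusted p = 4.57e-25 with the preset correlation, adjusted p = 0.0622 with an estimated correlation), with 9 lower adjusted over the list alone and 3 over all genes. Collagens had a median of -1.03 (adjusted p = 3.96e-23; adjusted p = 0.14 with an estimated correlation), with 11 lower and 1 higher adjusted over the list alone and 4 lower over all genes.

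Of 35 lists 17 were called in NIR + MoS2 against NIR with the preset correlation, 3 higher and 14 lower, and 0 with an estimated correlation. Epithelial markers had a median of -0.66 (adjusted p = 2.41e-09; adjusted p = 0.0622 with an estimated correlation), with 3 lower adjusted over the list alone and 1 over all genes, KRT7 at -1.53 (adjusted p = 0.0156). KRT7 lost its call without NIR + MoS2 replicate 1 (0.168), NIR replicate 1 (0.166) or NIR replicate 2 (0.0918) and without the filter (0.141). Histones had a median of -0.25 (adjusted p = 0.0012; adjusted p = 0.14 with an estimated correlation), and 0 of them passed either adjustment.

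NIR + MoS2 against MoS2 compares cells with and without light, both given nanosheets. Inflammatory genes were higher as a group, with a median of 0.38 for the NF-kB and inflammatory cytokine list over 28 genes (camera adjusted p = 9.43e-18), which held with an estimated correlation (adjusted p = 0.027). Replication-dependent histones had a median of 0.55 over 14 genes (adjusted p = 9.08e-12), which held as well (adjusted p = 0.027 with an estimated correlation). Of the inflammatory genes 9 were higher adjusted over the list alone and 0 over all genes, and of the histones 2 and 0. By single genes limma called 0, with 235 at an unadjusted p under 0.05 against 567.95 expected by chance, and voom called 0. The 5 smallest p-values included ARC at 2.09 (adjusted p = 0.0776; 103 reads against 4), the chemokine CXCL2 at 2.06 (0.0776), IL1B at 1.94 (0.603), CCL2 at 0.94 and the secretory chaperone SCG5 at -1.18. CXCL2 had 22 reads against 0, at least 5.21-fold higher (95% exact lower limit). Without NIR + MoS2 replicate 1, ARC (0.0156), CXCL2 (0.0208) and IL1B (0.00383) were called, 3 genes in all.

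Of 35 lists 12 were called in NIR + MoS2 against MoS2 with the preset correlation, 5 higher and 7 lower, and the 10 besides the inflammatory and histone lists did not hold with an estimated correlation. Cell cycle and mitosis genes had a median of 0.16 (adjusted p = 0.00106; adjusted p = 0.606 with an estimated correlation), lost without NIR + MoS2 replicate 2 (0.057). Immediate-early genes had a median of 0.14 (adjusted p = 0.00234; adjusted p = 0.606 with an estimated correlation), lost with a mean RPKM of at least 5 (0.0579), without MoS2 replicate 2 (0.213) and NIR + MoS2 replicate 1 (0.0751). NRF2 antioxidant genes had a median of 0.08 (adjusted p = 0.00424; adjusted p = 0.606 with an estimated correlation), lost without MoS2 replicate 1 (0.579), NIR + MoS2 replicate 1 (0.108) and NIR + MoS2 replicate 2 (0.060). Integrated stress and unfolded protein response genes had a median of -0.22 (adjusted p = 9.01e-06; adjusted p = 0.606 with an estimated correlation), lost without NIR + MoS2 replicate 1 (0.832). Smooth muscle and myofibroblast markers had a median of -0.21 (adjusted p = 0.00147; adjusted p = 0.606 with an estimated correlation), lost without MoS2 replicate 1 (0.505) and NIR + MoS2 replicate 1 (0.493). Glycolysis and hypoxia genes had a median of -0.10 (adjusted p = 0.00152; adjusted p = 0.606 with an estimated correlation), lost without MoS2 replicate 1 (0.421) and NIR + MoS2 replicate 1 (0.471, turned). Focal adhesion and actin genes had a median of -0.09 (adjusted p = 0.00424; adjusted p = 0.606 with an estimated correlation), lost without MoS2 replicate 1 (0.74) and NIR + MoS2 replicate 1 (0.313). Matrix glycoproteins and proteoglycans had a median of -0.12 (adjusted p = 0.00474; adjusted p = 0.606 with an estimated correlation), lost without MoS2 replicate 1 (0.738) and NIR + MoS2 replicate 1 (0.239). YAP/TAZ targets had a median of -0.12 (adjusted p = 0.00783; adjusted p = 0.742 with an estimated correlation), lost without MoS2 replicate 1 (0.756), NIR + MoS2 replicate 1 (0.0751) and NIR + MoS2 replicate 2 (0.216). Integrins had a median of -0.19 (adjusted p = 0.0112; adjusted p = 0.606 with an estimated correlation), lost without the filter (0.323), without MoS2 replicate 1 (0.756), NIR + MoS2 replicate 1 (0.0751) and NIR + MoS2 replicate 2 (0.277). Adjusted over the list alone 1 immediate-early and 1 stress response gene were higher, and over all genes 0 of these members passed.

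The interaction asks whether the nanosheets acted differently under light. NF-kB and inflammatory cytokine genes had a median of 0.50 (camera adjusted p = 7.23e-06 with the preset correlation, adjusted p = 0.227 with an estimated correlation), with 1 higher adjusted over the list alone. CXCL2 at 2.15, ACTA2 at -1.11, the lipid transfer gene STARD5 at 1.51 and ATXN7L3B, a paralog of a chromatin adaptor, at 1.42 were among the smallest p-values, each with an adjusted p of 1.00. limma called 0 genes, with 171 at an unadjusted p under 0.05 against 567.95 expected by chance, and voom called 0.

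In the interaction 6 lists were called with the preset correlation, the inflammatory list higher and 5 lower, and 0 with an estimated correlation. The 5 were cytosolic ribosomal proteins (median -0.16, adjusted p = 0.000654), integrated stress and unfolded protein response (-0.16, 0.00623), smooth muscle and myofibroblast markers (-0.22, 0.00623), oxidative phosphorylation (-0.16, 0.00749) and matrix glycoproteins (-0.16, 0.00749), each with adjusted p = 0.978 with an estimated correlation. Adjusted over the list alone 1 smooth muscle marker was lower. Without NIR + MoS2 replicate 1 all 5 lost their calls, in the order given with 0.948, 0.873, 0.56, 0.873 and 0.292. The ribosomal list also lost its call without control replicate 1 (0.215), MoS2 replicate 2 (0.378) and NIR replicate 1 (0.0786), and the stress response list without control replicate 2 (0.116), MoS2 replicate 1 (0.134) and NIR replicate 2 (0.597). The smooth muscle list lost it without control replicate 2 (0.444), MoS2 replicate 1 (0.382) and NIR replicate 1 (0.346), oxidative phosphorylation without control replicate 1 (0.563), MoS2 replicate 2 (0.883) and NIR replicate 1 (0.476) and matrix glycoproteins without control replicate 2 (0.232), MoS2 replicate 1 (0.513) and NIR replicate 1 (0.186). The ribosomal list turned higher without MoS2 replicate 2 or NIR + MoS2 replicate 1, and oxidative phosphorylation without MoS2 replicate 2.

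The MoS2 average over light compares the 4 libraries with nanosheets with the 4 without. SPP1 rose by 1.94 (SE 0.18, adjusted p = 0.000108), ESM1 by 2.12, GPNMB by 1.66, AKR1C1 by 1.65, TNFSF4 by 1.6 and TFPI2 by 1.56. On the lower side SAA1 changed by -2.07, HSPB7 by -1.92, LBH by -1.92, PPP1R14A by -1.92, CLIC3 by -1.91 and SAA2 by -1.97, the last from 41 reads to 1. The naming rule required 4 of 4 libraries with MoS2 beyond the 4 without, so for these 12 genes this was fixed by their choice. In RPKM (mean ± SD, n = 2), SPP1 (Entrez 6696; GRCh38 chromosome 4, 87975650 to 87983426) was at 6.34 ± 0.139 in control, 27.6 ± 8.42 in MoS2, 6.36 ± 0.387 in NIR and 37.2 ± 6.74 in NIR + MoS2. GPNMB (Entrez 10457; chromosome 7, 23235967 to 23275108) was at 6.0 ± 0.366, 29.4 ± 6.46, 9.7 ± 1.33 and 33 ± 10.8, and AKR1C1 (Entrez 1645; chromosome 10, 4963253 to 4983283) at 3.73 ± 0.753, 21.4 ± 6.27, 10.1 ± 0.181 and 31.8 ± 15, in the same order. limma called 423 genes, 298 higher and 125 lower, against 104 higher and 239 lower after centring, with 229 shared. voom called 472. Among the 423 was CXCL8 at 3.24 (limma adjusted p = 0.00141), above each rise given here. The naming rule passed it over, as 3 of 4 libraries with MoS2 lay above the 4 without. CCL2 at 0.87, IL1B at 1.18 and TNFAIP3 at 0.63 were called too, TNFAIP3 not after centring (0.0734), while IL6 was lower and not called as deposited. IL1B and TNFAIP3 did not keep their calls in every leave-out. Without the filter 129 were called, where PPP1R14A was not (0.0561), and the GC and length correction gave 1395.

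SPP1, ESM1 and the other genes that the rule named by size for this average kept their calls whichever library was left out. The number of genes called moved with single libraries. Without control replicate 1 the count for the MoS2 average was 207, without control replicate 2 it was 1433, and without NIR + MoS2 replicates 1 and 2 it was 212 and 1395. It was 107 without MoS2 replicate 2, 155 without NIR replicate 1 and 184 without NIR replicate 2. Without MoS2 replicate 1 it was 298, within a factor of 1.5 of the full count.

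COL1A1, ACTA2 and 9 other named matrix, contractile and adhesion genes were lower in the MoS2 average. COL1A1 (Entrez 1277; chromosome 17, 50183289 to 50201632) changed by -1.59 (adjusted p = 0.00159), COL16A1 by -1.45, the basement membrane collagen COL4A1 by -1.44, COL8A2 by -1.42 and the collagen-binding glycoprotein SPARC by -1.21. ACTA2 (Entrez 59; chromosome 10, 88935074 to 88991339) changed by -1.41 (adjusted p = 0.000271), CNN1 by -1.51 and enteric smooth muscle actin ACTG2 by -1.5. The collagen receptor chain ITGA11 changed by -1.33 and the laminin receptor chain ITGA7 by -1.42, and the focal adhesion protein LIMS2 by -1.04. All 11 had 4 of 4 libraries with MoS2 below the 4 without and kept their calls in every leave-out, while without the filter ITGA7 lost its call (0.0816). ACTA2 was at 1379.8 ± 26.3 RPKM (n = 2) in control, 864 ± 1.5 in MoS2, 1925 ± 119.8 in NIR and 580.1 ± 17.3 in NIR + MoS2. The rule also took MFAP4, FBLN5, LMOD1, TAGLN and TPM2, called lower, and LAMA4, called higher, from these lists. Unlike the 11 genes, they did not keep their calls in every leave-out.

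Of 35 lists 16 were called in the MoS2 average with the preset correlation, 4 higher and 12 lower, and 0 with an estimated correlation. Collagens had a median of -0.91 (camera adjusted p = 6.91e-23 with the preset correlation, adjusted p = 0.127 with an estimated correlation). Adjusted over the list alone 14 were lower and 2 higher, and over all genes 11 were lower. Of the 11, COL1A2, COL3A1, COL5A3, COL11A1 and COL12A1 did not keep their calls in every leave-out. Smooth muscle and myofibroblast markers had a median of -0.82 (camera adjusted p = 2.20e-22 with the preset correlation, 0.088 with an estimated correlation), with 11 lower adjusted over the list alone and 9 over all genes. Of the 9, LMOD1, RGS5, SYNPO2, TAGLN, TPM1 and TPM2 did not keep their calls in every leave-out. Matrix glycoproteins and proteoglycans had a median of -0.41 over 35 genes (adjusted p = 2.25e-13; adjusted p = 0.088 with an estimated correlation), with 10 lower adjusted over the list alone, 5 lower over all genes, and 1 higher by each adjustment. Integrins had a median of -0.27 over 15 genes (adjusted p = 0.000302; adjusted p = 0.209 with an estimated correlation), with 2 lower by each. Focal adhesion and actin genes had a median of -0.29 over 50 genes (adjusted p = 4.41e-12; adjusted p = 0.127 with an estimated correlation), with 7 lower adjusted over the list alone and 5 over all genes. TGF-beta response genes had a median of -0.32 over 26 genes (adjusted p = 1.04e-05; adjusted p = 0.291 with an estimated correlation), with 5 lower and 4 higher adjusted over the list alone and 3 and 1 over all genes, where the BMP target ID1 rose by 0.89. Chondrogenic genes had a median of -0.62 over 6 genes (adjusted p = 0.000376; adjusted p = 0.238 with an estimated correlation), with 3 lower adjusted over the list alone and 1 over all genes. Osteogenic genes had a median of -0.29 over 14 genes (adjusted p = 0.00402; adjusted p = 0.245 with an estimated correlation) but a mean of 0.018 as deposited, with SPP1 higher and COL1A1 lower, and 2 lower and 1 higher adjusted over the list alone and 1 and 1 over all genes.

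Cytosolic ribosomal protein and histone genes, whose levels can follow RNA quality, were called as lists in these comparisons with the preset correlation and not with an estimated one. The ribosomal list had a median of 0.13 over 76 genes in MoS2 against control (adjusted p = 6.36e-05; adjusted p = 0.697 with an estimated correlation), lost without MoS2 replicate 2 (0.877), and 0.04 in the MoS2 average (adjusted p = 0.00402; adjusted p = 0.731 with an estimated correlation). In the average the call was lost after centring (0.298) and without MoS2 replicate 2 (0.391), NIR + MoS2 replicate 2 (0.758) or NIR replicate 2 (0.0748), and 0 ribosomal genes passed over all genes. Histones had a median of -0.28 in MoS2 against control (adjusted p = 0.000401; adjusted p = 0.176 with an estimated correlation), with 2 lower adjusted over the list alone. In the average their median was -0.43 (adjusted p = 8.14e-05; adjusted p = 0.0947 with an estimated correlation), and HIST1H1C was called at -0.93 (adjusted p = 0.00955), though not without NIR replicate 1 (0.0729). RNA quality was not measured in the table.

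The antioxidant genes HMOX1, AKR1B10 and NQO1 and the ferritin gene FTH1 rose in the MoS2 average. HMOX1 (Entrez 3162; chromosome 22, 35380361 to 35394214) rose by 0.67 (adjusted p = 0.00588), FTH1 by 0.99, the aldo-keto reductase AKR1B10 by 1.39 and the quinone reductase NQO1 by 0.69, each higher in 4 of 4 libraries and called in every leave-out, while without the filter FTH1 (0.0541) and AKR1B10 (0.0514) lost their calls. HMOX1 was at 16.4 ± 3.4 RPKM (n = 2) in control, 29 ± 3.92 in MoS2, 24.9 ± 0.278 in NIR and 49 ± 2.25 in NIR + MoS2. The NRF2 list had a median of 0.21 (camera adjusted p = 7.00e-07 with the preset correlation, adjusted p = 0.185 with an estimated correlation). Adjusted over the list alone 19 were higher, and 9 over all genes. Of the 9, SLC7A11 (limma adjusted p = 0.0943), SQSTM1 (0.0641) and TXN (0.227) were not called after centring. Metallothioneins and metal handling genes had an adjusted p of 0.108, with 6 higher adjusted over the list alone and 2 over all genes. The lysosomal protease CTSK rose by 1.08 (adjusted p = 0.00188) and the plasminogen activator PLAT by 0.71, both in 4 of 4 libraries. In the same list of matrix proteases, inhibitors and crosslinkers SERPINE2 was called lower at -0.94 (limma adjusted p = 0.0119). PLAU was lower in 4 of 4 libraries and not called. Cell cycle and mitosis genes had a median of 0.28 (camera adjusted p = 2.57e-05 with the preset correlation, 0.30 with an estimated correlation). Adjusted over the list alone 17 were higher, and 1 over all genes, AURKB, which was not called after centring (limma adjusted p = 0.0504). Glycolysis and hypoxia genes had a median of -0.39 (adjusted p = 2.39e-11; adjusted p = 0.127 with an estimated correlation), with 3 lower adjusted over the list alone and 1 over all genes.

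**Figure D3:**
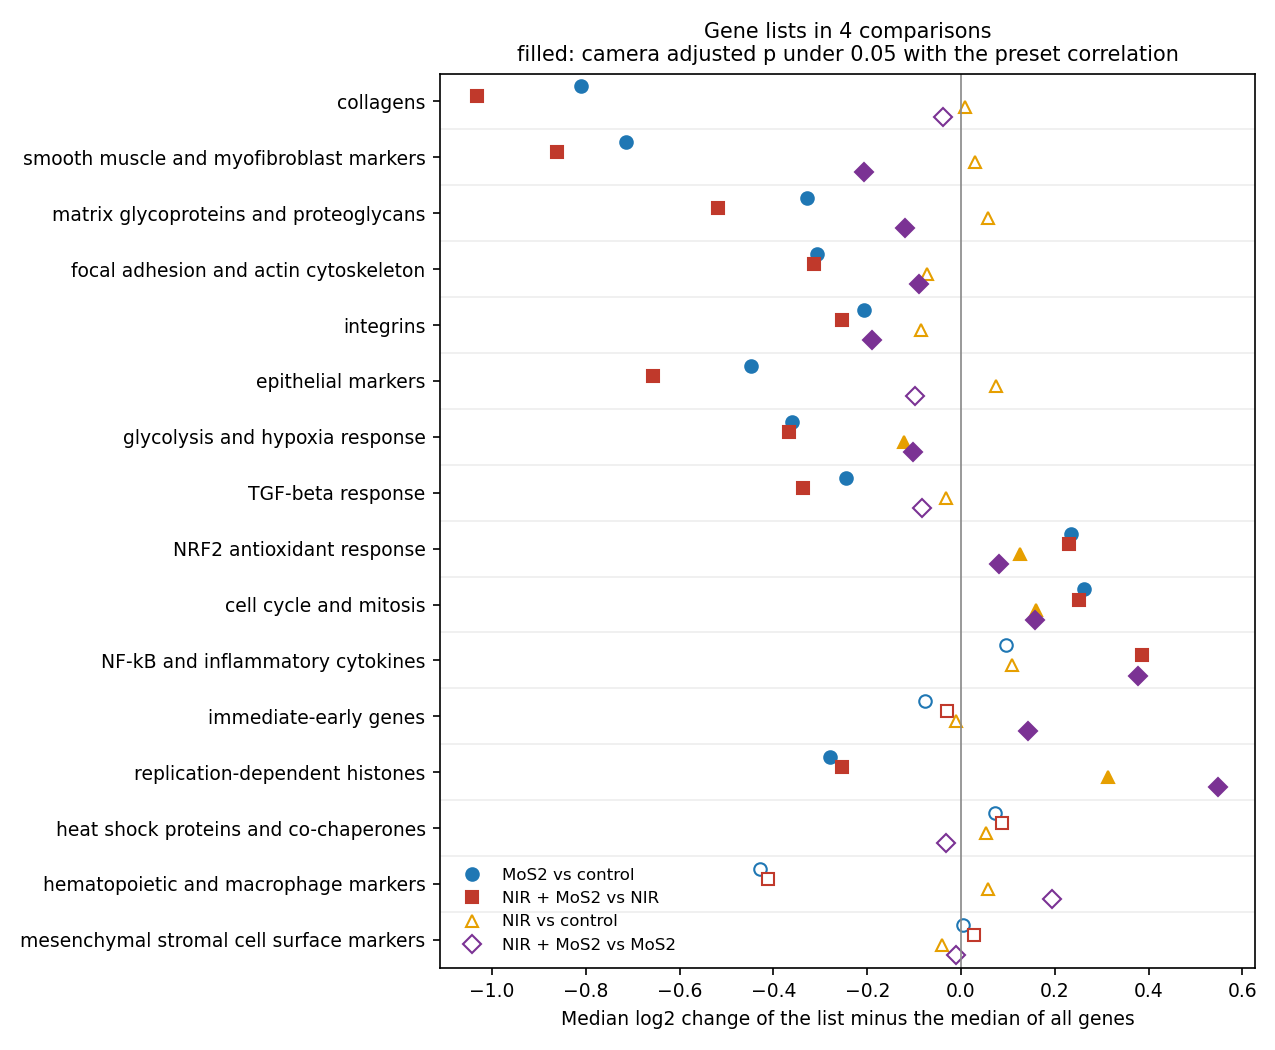
Median log2 change of 16 gene lists minus that of all genes in 4 comparisons; filled symbols mark a camera adjusted p under 0.05 with the preset correlation. Collagens lie at -0.81 for MoS2 against control and -1.03 for NIR + MoS2 against NIR, and NF-kB genes at 0.38 for NIR + MoS2 against MoS2.

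The NIR average over MoS2 compares the 4 libraries with light with the 4 without. ARC rose by 2.17 (SE 0.22, adjusted p = 0.00124), from 7 to 206 reads, a ratio of 29.5 (95% exact interval 14.1 to 74.2), and 4 of 4 libraries with NIR lay above the 4 without. ARC (Entrez 23237) was at 0.131 ± 0.0803 RPKM (n = 2) in control, 0.19 ± 0.026 in MoS2, 4.45 ± 1.13 in NIR and 4.41 ± 1.81 in NIR + MoS2. It was the 1 gene called by limma, by voom and after centring, and it kept its call in all 8 leave-outs, where the count was 2 without NIR replicate 1 or without NIR + MoS2 replicate 1. ARC lost its call without the filter on low values (adjusted p = 0.0701), and a mean RPKM of at least 5, which leaves ARC out, gave 0 genes; the replicate block gave 2. Replication-dependent histones had a median of 0.43 (camera adjusted p = 5.87e-15; adjusted p = 0.0323 with an estimated correlation), with 7 higher adjusted over the list alone and 0 over all genes. NF-kB and inflammatory cytokine genes had a median of 0.25 (camera adjusted p = 4.73e-12, and 0.0323 with an estimated correlation). Of these genes 6 were higher adjusted over the list alone and 0 over all genes. The inflammatory list was not among those called in NIR against control. CCL2, CXCL2 and CXCL8 lay above the 4 libraries without light in 2 of 4 libraries with light, and IL1B in 3 of 4. The average therefore does not show that light without nanosheets raised these genes.

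Of 35 lists 10 were called in the NIR average with the preset correlation, 5 higher and 5 lower, and the 8 besides the inflammatory and histone lists did not hold with an estimated correlation. Cell cycle and mitosis genes had a median of 0.17 (adjusted p = 3.76e-05; adjusted p = 0.669 with an estimated correlation), lost without control replicate 1 (0.087). NRF2 antioxidant genes had a median of 0.089 (adjusted p = 3.76e-05; adjusted p = 0.669 with an estimated correlation). Immediate-early genes had a median of 0.067 (adjusted p = 0.0258; adjusted p = 0.752 with an estimated correlation), lost with a mean RPKM of at least 5 (0.324), after the GC and length correction (0.0709), without control replicate 2 (0.787), MoS2 replicate 2 (0.25), NIR + MoS2 replicate 1 (0.115), NIR + MoS2 replicate 2 (0.0698) and NIR replicate 2 (0.0815). Glycolysis and hypoxia genes had a median of -0.10 (adjusted p = 6.07e-05; adjusted p = 0.669 with an estimated correlation), lost without NIR + MoS2 replicate 1 (0.716). Focal adhesion and actin genes had a median of -0.076 (adjusted p = 0.000548; adjusted p = 0.669 with an estimated correlation), lost without control replicate 1 (0.225) and MoS2 replicate 1 (0.0805). Integrated stress and unfolded protein response genes had a median of -0.12 (adjusted p = 0.00563; adjusted p = 0.752 with an estimated correlation), lost without NIR + MoS2 replicate 1 (0.771) and NIR replicate 1 (0.478). YAP/TAZ targets had a median of -0.12 (adjusted p = 0.00938; adjusted p = 0.784 with an estimated correlation), lost without control replicate 1 (0.394), MoS2 replicate 1 (0.324), NIR + MoS2 replicate 2 (0.0725) and NIR replicate 1 (0.34). Integrins had a median of -0.14 (adjusted p = 0.00942; adjusted p = 0.669 with an estimated correlation), lost without the filter (0.321), after the GC and length correction (0.0709), without control replicate 1 (0.103), MoS2 replicate 1 (0.324) and NIR + MoS2 replicate 2 (0.0864). Adjusted over the list alone 3 NRF2, 3 immediate-early and 1 stress response gene were higher, and over all genes 0 of these members passed; ARC is not in the immediate-early list tested.

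The MoS2 change without light and the MoS2 change under light share no libraries. SPP1, GPNMB and ACTA2 lay on the same side of 0 in both. This had to be so, as each had 4 of 4 libraries with MoS2 beyond the 4 without, and it adds no support. Across 11359 genes the changes as deposited had a Pearson r of 0.568 and a Spearman rho of 0.499, 75.8% had the same sign, and r was 0.415 to 0.550 with 1 library left out. Called in both were 11 genes, 7 higher and 4 lower, where 0.0343 and 0.0134 were expected from independent draws. Both comparisons use the same estimate of spread for each gene, so their calls are not independent and the expected numbers may be too low. The NIR changes without and with MoS2 had an r of 0.102 and a rho of 0.0684, with 52.2% of the same sign and a range from -0.0460, without MoS2 replicate 1, to 0.213. Genes are not independent replicates, so no p-value is given for these correlations. Comparisons that share the controls were set against 50 simulations with no change in any group. The covariance of the MoS2 and NIR + MoS2 changes against control was 0.108, against 0.0421 simulated, that of MoS2 and NIR was 0.0402 against 0.0422, and that of NIR and NIR + MoS2 was 0.0461 against 0.0423. Called in both MoS2 and NIR + MoS2 against control were 13 genes. The simulations gave 0, but with no change in any group hardly any gene can be called, so they cannot judge this overlap.

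**Figure D4:**
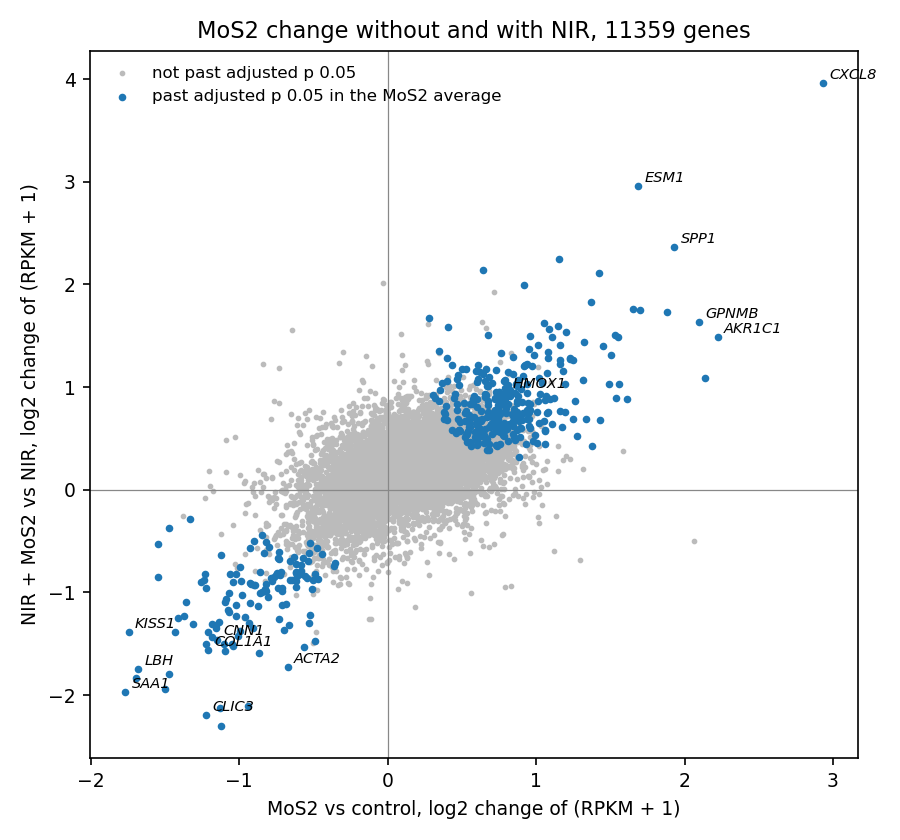
Log2 change of RPKM + 1 as deposited for MoS2 against control (horizontal) and NIR + MoS2 against NIR (vertical), 1 point per tested gene; blue points passed an adjusted p of 0.05 in the MoS2 average over light. Across genes r was 0.568.

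HSPA1A, the heat-inducible HSP70, was chosen before the data were examined as a marker of heat, and it was called in none of the 8 comparisons. In NIR + MoS2 against control HSPA1A was at 0.10 (adjusted p = 0.479), and in the MoS2 average it was at 0.11 as deposited and -0.078 after centring, which flipped its direction. HSPA1A lay above both controls in 2 of 2 NIR and 2 of 2 NIR + MoS2 libraries. In the NIR average 3 of 4 libraries with light lay above the 4 without, and in the MoS2 average 1 of 4. The heat shock list had a median of 0.085 in NIR + MoS2 against control over 31 genes (camera adjusted p = 0.956), with 2 higher and 2 lower adjusted over the list alone and 1 and 1 over all genes. The metallothionein MT1X was at 0.037 in that comparison and 0.10 in the MoS2 average (adjusted p = 0.165). The cytokine IL6 was at -0.61 in the MoS2 average (adjusted p = 0.0916, 0.0395 after centring). The integrin chain ITGB1 was at 0.13 as deposited and -0.061 after centring in the MoS2 average, again a flip of direction (adjusted p = 0.635). The proliferation marker MKI67 was too low to be tested, with RPKM means of 0.296 ± 0.0195 in control, 0.555 ± 0.133 in MoS2, 0.32 ± 0.113 in NIR and 0.674 ± 0.0806 in NIR + MoS2 (n = 2).

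Besides the smooth muscle list, of the cell type marker lists only the epithelial one was called in the MoS2 average, and not with an estimated correlation. Epithelial markers had a median of -0.49 over 9 genes in the MoS2 average (adjusted p = 8.22e-08; adjusted p = 0.088 with an estimated correlation), with the keratins KRT7 at -1.32 and KRT14 at -1.51, both lower in 4 of 4 libraries, where KRT14 lost its call without the filter (0.0505). Hematopoietic and macrophage markers had 5 tested genes and an adjusted p of 0.34, with 2 higher adjusted over the list alone and 1 over all genes. MSC surface markers had a camera adjusted p of 0.918 over 15 genes, with 5 higher and 2 lower adjusted over the list alone and 3 and 1 over all genes. Of the 3, ANPEP (limma adjusted p = 0.259) and CD44 (0.16) were not called after centring. Reads of close relatives, such as AKR1C1 and its paralogs, SAA1 and SAA2, CXCL1 and CXCL2, HSPA1A and HSPA1B, the MT1 genes and FTH1 pseudogenes, cannot be told apart from the table, and neither can the strand of reads.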

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

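Voom, thinning and the correction for GC content and length were chosen only after the result was seen. Of 136 named gene values that were called, the direction was kept with the pseudocount, without the filter, with the higher filter (117 tested), after centring, with the block, with voom, after the GC and length correction and in the leave-outs. Fits to only the 2 groups and thinned reads were recorded for counts alone, not for single genes. The call was kept in 131 with a pseudocount of 0.25, 117 of 117 with a mean RPKM of at least 5, 129 after centring, 130 with the replicate block, 115 with voom, 135 after the GC and length correction, 29 without the filter, and 512 of 728 values with 1 library left out. Of 99 list calls, 99 were kept with the pseudocount and with the block, 93 after centring, 92 after the GC and length correction, 88 without the filter, 4 with an estimated correlation and 12 with fry.

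Without the filter the genes called became 0 for MoS2 against control, 0 for NIR + MoS2 against control, 1 for NIR + MoS2 against NIR, 129 for the MoS2 average and 0 for the NIR average. The GC and length correction gave 35, 394, 193 and 1395 for the first 4 of these. Median centring gave 42 for MoS2 against control, 118 for NIR + MoS2 against NIR and 1 for NIR against control, where a pseudocount of 0.25 gave 1 and a fit to only the 2 groups 2. A mean RPKM of at least 5 gave 0 for the NIR average, as ARC then falls below the filter. With the replicate number as a block, so that equal numbers were treated as pairs, the counts were 28 for MoS2 against control, 1 for NIR against control and 2 for the NIR average, and 113, 74 and 350 for NIR + MoS2 against control, NIR + MoS2 against NIR and the MoS2 average. The correlation of MoS2 changes without and with light was 0.504 with a pseudocount of 0.25 and 0.672 with a mean RPKM of at least 5. Apart from ARC and the filter the cause was not tested.

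With 1 library left out the counts ranged from 0 to 523 for MoS2 against control, 15 to 769 for NIR + MoS2 against control, 0 to 3 for NIR + MoS2 against MoS2, 6 to 165 for NIR + MoS2 against NIR, 0 to 1 for the interaction, 107 to 1433 for the MoS2 average and 1 to 2 for the NIR average. The correlations of independent changes ranged from 0.415 to 0.55 for MoS2 and from -0.046 to 0.213 for NIR. Log2 changes as deposited changed sign in these leave-outs for genes that were not called. HSPA1A ranged from -0.000407 to 0.22 for MoS2 against control, -0.0547 to 0.291 for NIR + MoS2 against NIR and -0.164 to 0.181 for the interaction. ITGB1 ranged from -0.0123 to 0.356 for MoS2, -0.319 to 0.20 for NIR and -0.285 to 0.344 for NIR + MoS2 against control, -0.457 to 0.172 against MoS2, -0.225 to 0.404 against NIR, -0.397 to 0.232 for the interaction, -0.0268 to 0.288 for the MoS2 average and -0.258 to 0.0563 for the NIR average. MT1X ranged from -0.172 to 0.189 for NIR against control, -0.274 to 0.0872 for the interaction and -0.128 to 0.0523 for the NIR average. COL1A1 ranged from -0.0204 to 0.331 for NIR against control, -0.568 to 0.176 for NIR + MoS2 against MoS2, -0.723 to 0.0208 for the interaction and -0.206 to 0.166 for the NIR average. IL6 ranged from -0.0407 to 0.298 for NIR + MoS2 against MoS2 and -0.336 to 0.0019 for the interaction, where HMOX1 ranged from -0.0493 to 0.353.

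After centring HSPA1A turned to -0.0393 for MoS2 against control, -0.117 for NIR + MoS2 against NIR, -0.0777 for the interaction and -0.0781 for the MoS2 average, and ITGB1 to -0.188 for NIR + MoS2 against control, -0.146 against NIR and -0.0615 for the MoS2 average. After the GC and length correction MT1X turned to -0.042 for NIR against control, ITGB1 to -0.0707 and -0.00351 for NIR + MoS2 against control and against NIR, HSPA1A to -0.105 for the interaction and COL1A1 to 0.000122 for the NIR average.

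Lists that turned sign with 1 library left out had adjusted p from 1.46e-07 to 0.679 for cytosolic ribosomal proteins in NIR + MoS2 against control and 4.58e-15 to 0.948 in the interaction, 1.23e-07 to 0.883 for nuclear-encoded oxidative phosphorylation in the interaction, 2.32e-09 to 0.471 for glycolysis and hypoxia response in NIR + MoS2 against MoS2, and 6.36e-05 to 0.986 for the integrated stress response and unfolded protein response in NIR + MoS2 against NIR. Fry, which tests balance within a list, gave the other sign for matrix proteases, inhibitors and crosslinkers in MoS2 against control (adjusted p = 0.978), NIR + MoS2 against control (0.613), NIR + MoS2 against NIR (0.556) and the MoS2 average (0.622). It did so for YAP/TAZ targets in NIR + MoS2 against control (0.953), osteogenic differentiation in NIR + MoS2 against NIR (0.77) and the MoS2 average (0.88), and for the integrated stress response and unfolded protein response (0.656) and adipogenic differentiation (0.383) in NIR + MoS2 against NIR. MKI67, at 21 to 78 reads per library, fell below the RPKM filter. With reads thinned to the smallest library the MoS2 average had 407 calls and NIR + MoS2 against control 116.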

Other observations

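Genes outside the rule for naming, chosen after their values were seen, were called in the MoS2 average and kept their calls after centring and with each library left out (log2 relative to the median gene). The interferon-induced gene IFIT3, whose product binds viral RNA sensors, rose by 1.22 (adjusted p = 0.00278), and AOX1, an aldehyde oxidase that carries a molybdenum cofactor, by 0.73 (0.00533). The tetraspanin CD9 rose by 0.66 (0.00334) and the metallothionein MT1E, which binds zinc and copper, by 0.59 (0.00361). The small heat shock protein CRYAB, a chaperone of desmin filaments, fell by 1.21 (0.00177). Each showed its direction in 4 of 4 libraries with MoS2.

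Of the tests that follow, those on GC content and length, on depth by thinning, on scaling by total reads, on immune cells, on a single library and on macrophages were chosen only after the result was seen. Collagen and contractile genes (36 tested members of both lists) had a median change of -0.88 with MoS2, and 20 were called lower. Many of the 20 did not keep their calls in every leave-out, such as COL3A1, COL11A1, LMOD1 and SYNPO2 without MoS2 replicate 2. Differences in GC content and length between libraries are argued against as the whole cause, since the median was -0.85 after their removal, from -0.93 to -0.75 with 1 library left out, and 20 of the 20 stayed called. Depth is argued against, since thinning to the smallest library left at least 19 of the 20 called in 5 draws. The authors' scaling by total reads stays open: 20 stayed called after centring, which by the bound as first written (at least 0.75 of the 20) counts against scaling, but centring takes 0.192 off each change and could not have ended a lower call by size, so after the value had been seen the test was read as deciding nothing, and whether absolute levels fell is not known. A response to the nanosheets, RNA quality and a difference between cultures or processing days that follows the groups stay open as well, and the last 2 were not tested.

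NF-kB and inflammatory genes were higher in NIR + MoS2 than in MoS2, with a median of 0.377. Immune cells in the cultures are argued against, since IL1B rose by 30.6 RPKM while the largest rise among the abundant transcripts LYZ, CD74, TYROBP, HLA-DRA, LAPTM5 and FCER1G was 0.314, in LAPTM5. Of these 6 genes FCER1G was at 4.22 RPKM in MoS2 and 4.25 in NIR + MoS2, and the others were under 1 in both. A single library is argued against, since the median was 0.372 at its lowest, without MoS2 replicate 2, and 0.417 at most without an NIR + MoS2 library. A response to light of cells given nanosheets may explain it. The interaction was called for 0 single genes by limma and by voom. At an unadjusted p under 0.05 limma gave 171, with 567.95 expected by chance. A difference in the light effect with and without nanosheets therefore stays open. The histone list, whose levels can follow RNA quality, was also higher in this comparison and held with an estimated correlation. RNA quality was not tested and stays open.

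GPNMB, SPP1 and CTSK, which macrophages and osteoclasts also express, rose with MoS2. Macrophages in the cultures are argued against, since GPNMB rose by 23.3 RPKM while the largest rise among PTPRC, CSF1R, TYROBP, CD163, C1QA, LAPTM5, CD74 and LYZ was 0.0717, in LYZ. CD68, a lysosomal gene of macrophages left out of that set and chosen here after its values were seen, rose by 0.39 (adjusted p = 0.0257, 0.185 after centring, 0.164 without MoS2 replicate 2), from 46.9 ± 0.392 and 54.2 ± 6.71 RPKM in control and NIR to 69.4 ± 6.65 and 85.5 ± 9.62 in MoS2 and NIR + MoS2 (n = 2), while TYROBP, CD163 and C1QA were at 0 in all libraries. A rise of lysosomal genes as a class may lie behind them and stays open, with camera p = 0.199 under an estimated correlation for 44 lysosomal hydrolases and V-ATPase subunits outside the earlier lists, a median change of 0.0472, with 0.00654 to 0.0472 when 1 library was left out, and 2 called higher (3 adjusted over the list alone). The bound written beforehand, 0.05, was met by less than this spread, and how the spread enters was settled after the value had been seen; read without it, the bound argues against the class.

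DUSP6, ESM1 and HMGA1 rose with MoS2, and a rise of ERK pathway feedback genes as a class was a hypothesis. Over 12 other feedback genes camera gave p = 0.789 under an estimated correlation, with a median of 0.0149 and -0.0973 to 0.136 with 1 library left out. The class was not shown to rise, and since the spread crosses the bound of 0.05 the explanation may still hold for part of it, with the same caveat on how the spread enters.

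Chance is argued against, not excluded, for the number of genes called in the MoS2 average if the 8 libraries are independent, which the labels do not say. A fit of 2 sets of 4 libraries called 874 genes for the real split and 1 gene at most for the others. Thus 1 of the 35 splits, the real one, reached the real count, the smallest share that 35 splits can give. If the 2 libraries of a group share a culture, only splits by whole groups are left, too few for a share under 0.05. For the NIR average the splits cannot give a share under 0.05, as the split by MoS2, a structure of the samples, is always among those that exceed it. The real split called 1 gene, the highest other 874, and 2 of the 35 splits reached the real count. This reading was settled after the value had been seen; by the prediction written beforehand the share, above 0.05, would have counted for chance.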
